A study of Arabidopsis thaliana with 24 samples.

How the data were processed

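Affymetrix ATH1 arrays were read from 24 samples of total RNA from Arabidopsis thaliana Col-0, 12 groups of 2 arrays defined by tissue (shoots or roots) and time at 4 °C. Each array's group and replicate number came from the sample titles. The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes. The version and settings of MAS5 and its detection calls are not given in the sources used here. On every array the mean of the deposited intensities, trimmed by 2% at each end, was 100, so each array had been scaled to the same target. A scaling of this kind can move the share of genes called higher or lower where the spread of intensities differs between arrays. Median intensity was 29.8 to 39.7 on shoot arrays and 35.3 to 47.8 on root arrays, and was lowest on the 24 h shoot arrays (29.8 and 30.3).

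The values were kept as deposited, a pseudocount of 10 (0.1 of the trimmed mean) was added and log2 was taken. Fold changes are on this log2(value + 10) scale, which understates the change of dim genes and so sets the rank of those that start or end near the floor. After 64 control probe sets were set aside, 22746 remained, and the 16072 with an intensity of at least 30 on at least 2 of the 24 arrays were tested. Gene names came from the platform annotation, which pairs 13513 probe sets with 1 gene, 503 with several and lists no gene for 8730. Probe sets with several genes or none were tested but not named, so many familiar cold genes were not analysed here. Of the tested probe sets 8744 had 1 gene, for 8651 genes, and 7414 of these are known by locus only. Of the named probe sets 13436 were matched to the reference gene table by gene ID. Where a gene had several probe sets, the one with the highest mean log2 value was used for named genes and lists.

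Differences were tested with limma (version 3.58.1, in R 4.3.3), by a linear model of the 12 group means over all 24 arrays with 12 residual degrees of freedom and an empirical Bayes prior of 4.9 degrees of freedom. All tests were 2-sided. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was called. Compared were 1, 3, 6, 12 and 24 h against 0.5 h within each tissue, the difference between tissues in the 3 h and 24 h change, and roots against shoots over all times. The overlap of the 24 h calls was set beside the product of the list sizes over the number tested. Comparisons within a tissue share the 0.5 h arrays, so no overlap or correlation between times was computed. Groups, comparisons and their tests, 17 gene lists and most alternatives were chosen before the data were examined, and 8 further lists and most tests of explanations only afterwards.

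Named genes had exactly 1 gene in the annotation, passed the threshold, and had both arrays of a group beyond both arrays of the other. Ranked by log2 change, the 8 highest and 8 lowest at 24 h and the 5 highest and 5 lowest at 3 h were taken in each tissue. For the tissue difference the 5 highest and 5 lowest at 24 h and the 3 highest and 3 lowest at 3 h were taken, without the demand on both arrays, and for roots against shoots the 6 highest and 6 lowest. From each list up to 4 members per comparison could be named.

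Of 17 lists fixed by locus (291 loci), 5 had at least 3 measured members: cold-regulated genes (6 of 19 loci), starch breakdown and soluble sugars (3 of 16), photosynthesis (5 of 27), ribosome biogenesis (8 of 22) and root markers (3 of 17). With 1 or 2 measured members there were 7: early cold transcription factors (1 of 17), flavonoid synthesis (2 of 20), circadian clock (1 of 22), heat shock (2 of 18), touch and wound (2 of 26), abscisic acid response (1 of 20) and DNA replication (1 of 16). Photoprotection, cold-shock and RNA-chaperone proteins, aquaporins, nitrate assimilation and membrane lipid genes had 0 named and tested members, so nothing is reported for these 5. A further 8 lists were added after the data were seen: chloroplast-encoded genes (69 of 69), nuclear photosynthesis genes (23 of 23, with all 5 of the fixed list), expansins and xyloglucan hydrolases (23 of 28, of which 2 are root markers), LEA proteins (6 of 8), endoplasmic reticulum folding genes (24 of 26), auxin genes (14 of 20), hypoxia genes (19 of 40, with CML38 of the touch list) and mitochondrion-encoded genes (11 of 16). The members of the added lists, the hypoxia list above all, come from general knowledge and were checked only against the annotation, so single members may be wrong. Lists with at least 3 members were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, in 156 tests adjusted together. Of these 43 passed, 29 up and 14 down. With a correlation estimated from the residuals 16 passed, 15 up and 1 down, which were cold-regulated genes from 3 h on, their tissue difference at 3 h, and LEA proteins in shoots from 3 h and in roots from 6 h. With fry, which asks whether a list's genes move 1 way on balance and makes no comparison with other genes, 40 passed, 28 of them shared with camera.

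Alternatives were quantile normalization over all arrays or within each tissue, centring each array on its median, pseudocounts of 1 and 30, no filter, a mean intensity of at least 100, a fit per tissue, an intensity trend with robust variances, a demand for a 2-fold change, the replicate number as a block, the mean of 0.5 and 1 h as baseline, and leaving out each array in turn. A baseline of 1 h, and leaving out both shoots 1 h replicate 1 and roots 3 h replicate 2, each from a pair that differed most, were added after seeing the data. The pipeline was tested on simulated data built on the 24 h against 0.5 h comparison in shoots, with 16072 genes. It recovered 82% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, with 13 false calls among 15872 unchanged genes. The changed genes were drawn from those above the median in mean log2 value, and the noise was independent between genes. In the real data 53.5% of probe sets were called in this comparison, so these rates are not those for dim genes or for the real data. No batch is given in the labels, so none was modelled. Probe-level files were not used here.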

Results

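Gene expression was measured in shoots and in roots of Arabidopsis thaliana, ecotype Col-0, during the first day of chilling. The plants grew on Murashige and Skoog medium at 24 °C with 16 h days and 50% humidity. On day 16, after 3 h of light, they were moved to 4 °C and were sampled after 0.5, 1, 3, 6, 12 and 24 h. Each of the 12 combinations of tissue and time was represented by 2 arrays, 24 in all, each holding 22810 probe sets of the ATH1 type. No untreated group was among these samples, so every change with time is given against 0.5 h in the cold. The 0.5, 1 and 24 h samples were taken within 1 h of each other by the time of day, and the 3, 6 and 12 h samples were not. At 3, 6 and 12 h, in shoots and in roots, time in the cold and time of day therefore cannot be told apart. The labels do not state that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 2 arrays per group, the number of arrays limits the precision. Between 11342 and 12724 probe sets per shoot array, and between 12189 and 13649 per root array, reached an intensity of 30. Replicate arrays correlated across probe sets with r from 0.951 to 0.991, and no pair held identical values. The SD of the log2 difference between replicates was 0.44 for shoots at 1 h and 0.47 for roots at 3 h, against 0.23 to 0.35 for the other groups.

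The tissue labels were checked with genes known to mark green tissue and root. Rubisco activase (RCA), which keeps the carbon-fixing enzyme active, had an intensity of 5230 ± 352 (SD, n = 12) in shoots and 138 ± 51 in roots. PYK10, a beta-glucosidase of root endoplasmic reticulum bodies, had 3389 ± 327 in roots and 569 ± 120 in shoots. The root hair expansins EXPA7 and EXPA18 were also higher in roots, by 1.86 and 1.61 on the log2 scale. All 5 measured photosynthesis genes were higher in shoots and all 3 measured root markers were higher in roots. Among the genes ranked outermost on the log2(value + 10) scale, the osmotin OSM34 reached 1562 ± 363 in roots and 4.42 ± 4.89 in shoots, a log2 difference of 6.79 ± 0.14 (SE; adjusted p = 2.9e-18). AT3G13610, an enzyme of scopoletin synthesis, and the peroxidase gene AT3G01190 were higher in roots by 6.34 and 6.16. In the other direction, AT1G23130 had 2.03 in roots and 2364 ± 234 in shoots (log2 difference −7.62 ± 0.06, adjusted p = 5.3e-23). The Calvin cycle enzyme SBPASE (−6.62 ± 0.09) and the photosystem II antenna protein LHCB4.2 (−6.65 ± 0.11) were far lower in roots. Over all times 13949 of 16072 probe sets differed between the tissues, 9259 higher and 4690 lower in roots, which is 66.4% higher. This split was 56.9% higher (7675 and 5811) when each array was centred on its median, and 59% higher (8086 and 5619) after quantile normalization.

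After 1 h in the cold, few of the genes followed here had changed in shoots. STZ, a zinc finger repressor that answers cold and salt, rose by 1.21 ± 0.25 (SE; adjusted p = 0.016), from an intensity of 235 ± 124 (SD, n = 2) to 520 ± 35. COR47, a dehydrin, rose by 1.10 ± 0.26 (adjusted p = 0.03) and was the 1 of 6 cold-regulated (COR) genes past the threshold, also when adjusted over the list alone (camera adjusted p = 0.26). Of the chloroplast-encoded genes, 17 of 69 rose and none fell, with 27 adjusted over the list alone, led by psaC at 2.98 ± 0.31 (camera adjusted p = 6.1e-11; with an estimated correlation, adjusted p = 0.7). Their list mean (log2) was 9.70 and 9.85 on the 0.5 h arrays and 10.61 on 1 h replicate 2, which stood 0.61 above 1 h replicate 1, and the 25S rRNA control read 212 and 246 at 0.5 h and 1862 and 1766 at 1 h. In all, 293 probe sets were higher and 160 lower than at 0.5 h. This count rested on single arrays: it was 112 and 147 without replicate 2 and replicate 1 at 0.5 h, and 118 and 2211 without replicate 1 and replicate 2 at 1 h. Without 1 h replicate 2 the larger side turned, with 860 higher and 1351 lower. Shoots 1 h replicate 1 and roots 3 h replicate 2, each from a pair that differed most, were also left out together, a choice made after seeing the data. A difference within a pair does not show which of its arrays deviates.

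By 3 h the changes in shoots against 0.5 h were broad among the genes that rose. The 3 h samples were taken later in the day, so time in the cold and time of day cannot be told apart. The 0.5 h arrays also stood apart in the 25S rRNA control (212 and 246, against 889 to 1862 on the other shoot arrays). With 1 h as the baseline, chosen after seeing the data, the 0.5 h arrays are left out of the comparison. The counts in shoots at 3, 6, 12 and 24 h were then 571, 2631, 5935 and 8242, in place of 1238, 3483, 6486 and 8606. Whether the 25S rRNA level has a part in this was not tested. AT5G62360, of the invertase and pectin methylesterase inhibitor family, went from 3.31 ± 0.332 (SD, n = 2) to 1331 ± 88.9, a log2 change of 6.65 ± 0.31 (SE; adjusted p = 1.3e-10). AT1G11210 rose by 5.53 ± 0.22 and AT1G51090 by 4.95 ± 0.25. AT4G27652 (19.7 to 1077 ± 5.15) and the calmodulin-like gene CML38 (46.2 ± 37.3 to 1469 ± 47.8) were back at 28.3 ± 5.03 and 38.7 ± 3.72 by 24 h. STZ reached 2112 ± 32.7 (3.21 ± 0.25, adjusted p = 9.7e-08), and the clock gene GI, whose loss delays flowering, rose by 1.26 ± 0.16 (adjusted p = 2.7e-05). Both measured genes of the touch and wound list, CML38 and the transcription factor gene WRKY53 (1.70 ± 0.32), rose. All 6 COR genes rose, also when adjusted over the list alone, with a median log2 change of 2.65 (camera adjusted p = 3.8e-16; with an estimated correlation, adjusted p = 0.00052). COR15B, whose product protects chloroplast membranes from freezing, rose by 3.55 ± 0.30 and COR47 by 3.25 ± 0.26. The declines were smaller, from −1.22 ± 0.23 for AT3G26510 to −1.43 ± 0.17 for P1R1 (202 ± 0.438 to 68.4 ± 0.915). In all, 851 probe sets were higher and 387 lower, and of these 488 and 24 changed at least 2-fold. The count of 1238 was 756, 765 and 780 without 0.5 h replicate 1, 0.5 h replicate 2 and 3 h replicate 2, and 571 with 1 h as the baseline, chosen after seeing the data.

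At 6 and 12 h in shoots the COR changes against 0.5 h were larger, and at 12 h declines outnumbered rises. These samples were taken later in the day than those at 0.5 h, so changes with the cold and with the time of day cannot be told apart. LTI30, a dehydrin, went from 19.8 ± 10.6 (SD, n = 2) at 0.5 h to 1928 ± 52.9 at 6 h and 5881 ± 223 at 12 h. AT4G33980 rose by 6.11 ± 0.17 (SE; adjusted p = 1.6e-13) at 6 h and COR27 by 6.90 ± 0.19 (adjusted p = 3.6e-14) at 12 h. The median of the 6 COR genes, all of which rose at both times, was 5.48 at 6 h and 6.55 at 12 h (camera adjusted p = 3.8e-16 and 4.6e-12). GI reached 1116 ± 16.1 at 12 h from 45.2 ± 11.9. PWD, a kinase that primes starch for breakdown, rose by 0.76 ± 0.14 at 6 h and 1.89 ± 0.14 at 12 h. STZ was still up at 6 h (2.66 ± 0.25) and had a change of 0.31 ± 0.25 (adjusted p = 0.35) at 12 h. LEA4-5, a late embryogenesis abundant protein gene of the abscisic acid list, had a change of 0.23 ± 0.29 (adjusted p = 0.62) at 6 h and rose by 2.76 ± 0.29 (adjusted p = 5.8e-07) at 12 h. Of the ribosome biogenesis genes 3 of 8 rose at 12 h (3 adjusted over the list alone; 6 with median centring and 4 after quantile normalization), with a camera adjusted p = 0.029 and an adjusted p = 0.74 with an estimated correlation. Totals were 1565 higher and 1918 lower at 6 h, and 2257 higher and 4229 lower at 12 h. The 6 h total of 3483 was 2214, 2236 and 2246 without 0.5 h replicate 1, 0.5 h replicate 2 and 6 h replicate 2. Which side was larger at 6 h turned with the setting: 1677 were higher and 1541 lower with median centring, 1638 and 1633 after quantile normalization and 813 and 290 at 2-fold or more, and with any 1 of the 4 arrays left out 50.8% to 54.8% were higher, against 44.9% as deposited. At 12 h, 34.8% of the calls were higher as deposited, 48.6% (2818 higher, 2980 lower) with arrays centred on their medians and 42.7% after quantile normalization.

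At 24 h in shoots several genes for protective proteins of cold-hardened tissue were among those ranked highest on the log2(value + 10) scale, where genes near the floor at 0.5 h are understated. LTI30 stood at 8297 ± 48.6 (SD, n = 2), a log2 change of 8.17 ± 0.22 (SE; adjusted p = 4.6e-14). LEA4-5 went from 2.42 ± 1 to 3483 ± 68.6 (8.14 ± 0.29, adjusted p = 5e-13) and COR15A from 40.3 ± 5.4 to 7290 ± 317 (7.19 ± 0.40, adjusted p = 1.5e-10). AT1G16850, AT5G62360, AT1G51090, AT1G11210 and COR27 rose by between 6.83 and 7.94. All 6 COR genes rose (6 adjusted over the list alone), with a median of 6.80, which is 7.0 above that of all genes (camera adjusted p = 1.6e-09; with an estimated correlation, adjusted p = 0.0024). EXPA8, an expansin that loosens cell walls, fell from 609 ± 5.45 to 11.7 ± 0.4 (−4.84 ± 0.33, adjusted p = 2.5e-09). AT1G23390, an F-box gene whose product marks chalcone synthase for removal, fell by 4.35, and the pectate lyase gene AT4G24780 fell by 4.17. AT4G33666 fell from 973 ± 0.728 to 21 ± 5.63 (−5.0 ± 0.25), and as its end, like that of EXPA8, lies under an intensity of 30, their order was not read. AT2G34620, AT1G13650, AT1G55960 and AT2G27420 fell by between 4.17 and 4.78.

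**Figure D1:**
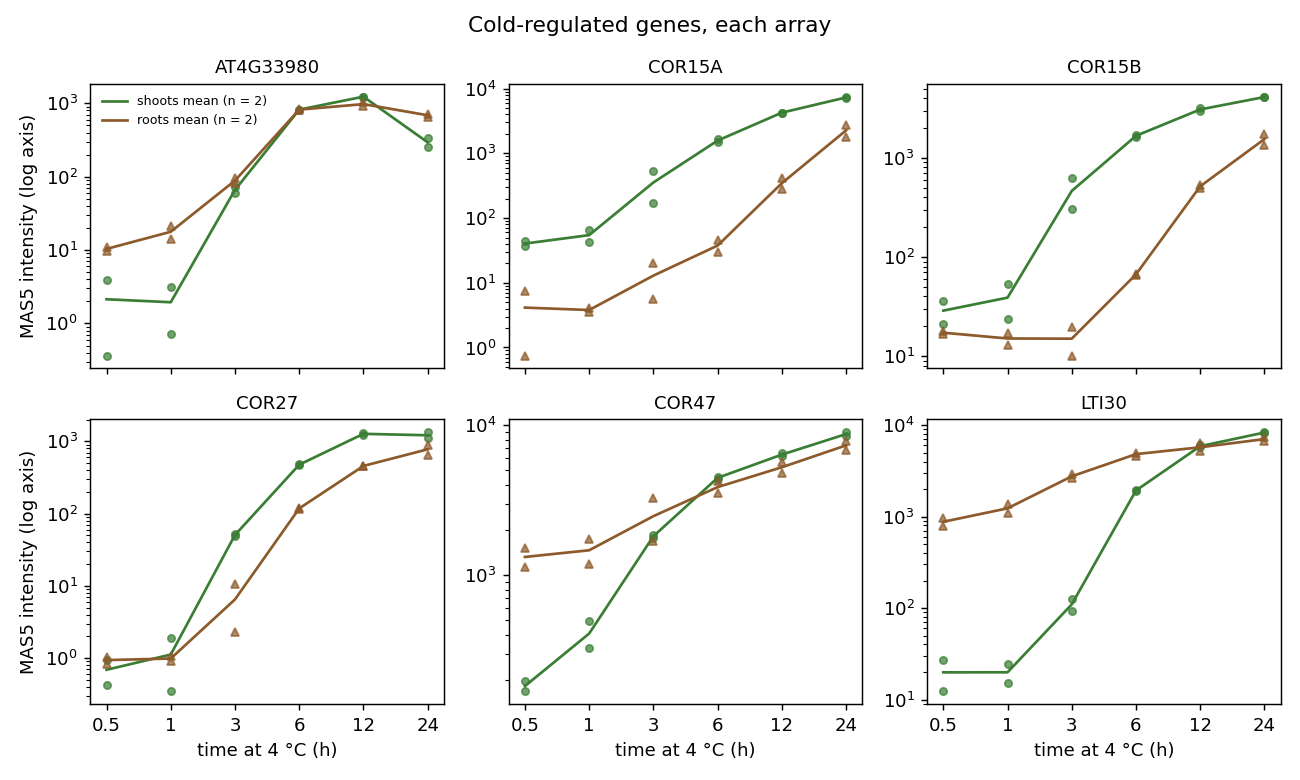
MAS5 intensity (log axis) of the 6 measured cold-regulated genes against time at 4 °C (h); points are single arrays and lines join the means of 2 arrays, green for shoots and brown for roots. LTI30 and COR47 start higher in roots (878 and 1323 at 0.5 h, against 19.8 and 182 in shoots), and at 24 h LTI30 reads 8297 in shoots and 7031 in roots, COR47 8723 and 7335.

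Other groups in shoots at 24 h moved together or split. All 8 measured ribosome biogenesis genes rose (8 adjusted over the list alone), with a median of 1.32, or 1.52 above all genes. AT5G14520, which encodes the pescadillo protein of the large subunit assembly pathway, went from 177 ± 31.3 (SD, n = 2) to 683 ± 73.2 (1.90 ± 0.20 SE, adjusted p = 4.9e-07), and the nucleolar helicase PRH75 rose by 1.37 ± 0.20. Camera gave an adjusted p = 2.4e-05 for this list, and an adjusted p = 0.18 with an estimated correlation. Of 3 starch genes 2 rose and none fell (2 adjusted over the list alone), PWD by 1.74 ± 0.14 and DPE1, which rearranges glucan chains, by 0.59 ± 0.16 (camera adjusted p = 0.075), and 3 rose after either rescaling. Of 5 photosynthesis genes 1 fell and 4 did not pass (1 adjusted over the list alone): LHCB4.2 went from 4757 ± 237 to 1456 ± 282 (−1.71 ± 0.27, adjusted p = 4.8e-05; camera adjusted p = 0.93). GI stood at 905 ± 100 (4.06 ± 0.16), and STZ was below its 0.5 h level (−0.79 ± 0.25, adjusted p = 0.014). AT5G48570, a peptidyl-prolyl isomerase of the heat shock list, fell by 1.05 (adjusted p = 0.0037), and the replication gene PRL fell by 0.51 (adjusted p = 0.015). The flavonoid genes DFR (−0.97 ± 0.47, adjusted p = 0.095) and UF3GT (−0.35 ± 0.30, adjusted p = 0.35) did not pass at this time or at any other. Of the 3 root markers PYK10 fell by 0.57 (adjusted p = 0.012; 1 adjusted over the list alone), and no root marker passed once arrays were centred on their medians. In all, 3094 probe sets were higher and 5512 lower, and of these 1510 and 2085 changed at least 2-fold. The median change over all genes was −0.20 in shoots and −0.21 in roots at 24 h, against −0.02 and −0.01 with median centring. The share higher in shoots was 36% as deposited, 49.7% (4009 higher, 4056 lower) with median centring and 44.9% (3601 and 4427) after quantile normalization.

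**Figure D2:**
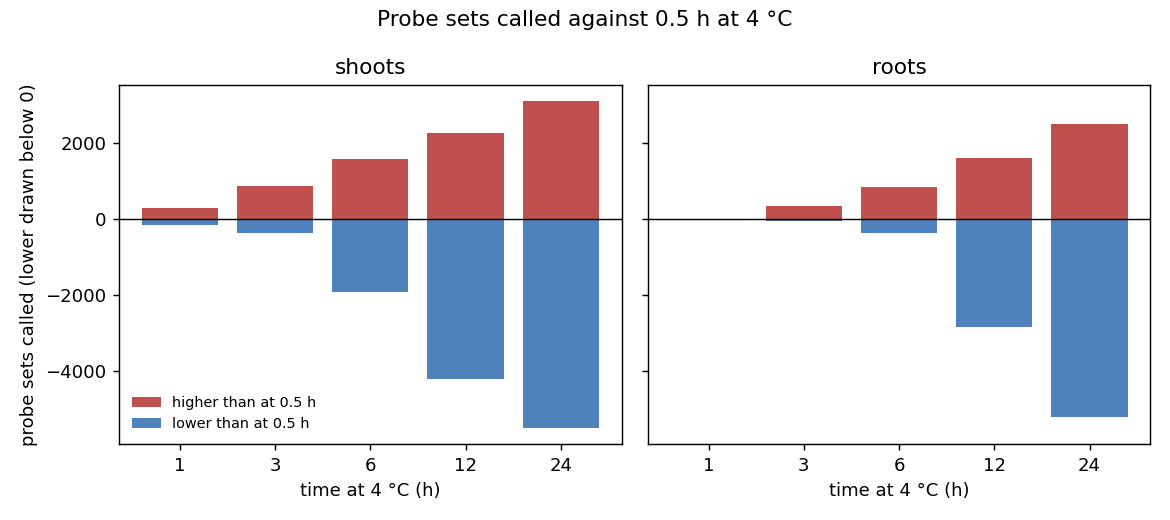
Number of probe sets past an adjusted p of 0.05 against 0.5 h at 4 °C (vertical axis, lower ones drawn below 0) at each time in h (horizontal axis), for shoots on the left and roots on the right. Counts grow with time in both tissues, to 3094 higher and 5512 lower in shoots and 2488 higher and 5222 lower in roots at 24 h.

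In roots at 1 h, 3 probe sets were higher than at 0.5 h and none lower by limma, with 366 at an unadjusted p under 0.05. The probe sets 254066_at, 254074_at and 254075_at have no gene listed in the annotation used here and were singled out after their values were seen. They went from 25.9 ± 3.81 (SD, n = 2) to 141 ± 16.6, from 2.32 ± 0.756 to 41.5 ± 0.787 and from 29 ± 1.77 to 246 ± 3.86. Their log2 changes were 2.08 ± 0.16 (SE), 2.06 ± 0.27 and 2.72 ± 0.24. None of the 6 COR genes passed, also when adjusted over the list alone (median 0.07, camera adjusted p = 0.12), and STZ had a change of 1.09 ± 0.25 (adjusted p = 0.6). Camera placed the 5 photosynthesis genes higher (adjusted p = 0.0076) with 0 members past the threshold, and gave an adjusted p = 0.74 with an estimated correlation. The nuclear photosynthesis list, which holds these 5, had means (log2) of 5.48 and 6.04 on the 0.5 h root arrays and 5.86 and 6.02 on the 1 h arrays, so 0.5 h replicate 2 was not below them. Leaving out single arrays gave between 2 and 4 calls, with 2 without 0.5 h replicate 1.

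At 3 h in roots AT5G62360 also rose, going from 6.89 ± 5.62 (SD, n = 2) to 231 ± 137 (3.75 ± 0.31 SE, adjusted p = 1e-06). AT1G11210 rose by 3.62 ± 0.22, AT5G11070 by 3.38 ± 0.31, AT1G25400 by 3.14 ± 0.28 and AT4G29780 by 2.90 ± 0.35. STZ rose by 2.15 ± 0.25 (adjusted p = 4.1e-05) and CML38 by 2.45 ± 0.51 (adjusted p = 0.012), while GI had a change of 0.32 ± 0.16 (adjusted p = 0.4). Of 6 COR genes, AT4G33980 (2.27 ± 0.17) and LTI30 (1.64 ± 0.22) rose, and 4 rose when adjusted over the list alone. The list median was 0.75 (camera adjusted p = 6.5e-07; with an estimated correlation, adjusted p = 0.0091). The declines were small, such as AT3G45210 from 111 ± 10.5 to 47.4 ± 4.52 (−1.08 ± 0.13, adjusted p = 8.6e-05). The declines of AT1G04770 (−1.34 ± 0.30, adjusted p = 0.017), AT5G57785 (−1.19 ± 0.25, adjusted p = 0.013), AT5G65860 (−0.99 ± 0.23, adjusted p = 0.024) and AT2G02630 (−1.03 ± 0.26, adjusted p = 0.046) lost their call under some settings or without single arrays. In all, 342 probe sets were higher and 51 lower. This total of 393 was 205, 232 and 1254 without 0.5 h replicate 1, 3 h replicate 2 and 3 h replicate 1, and without 3 h replicate 1 the larger side turned, with 568 higher and 686 lower. It was 256 without both roots 3 h replicate 2 and shoots 1 h replicate 1, and 162 with 1 h as the baseline, both chosen after seeing the data. On roots 3 h replicate 2, 20 of 23 nuclear photosynthesis genes were higher than on its partner, by a median of 0.68. Their mean (log2) of 6.19 on it lay near 6.04 and 6.02 on replicate 2 of 0.5 h and 1 h, and chloroplast-encoded transcripts were lower on it than on its partner, by a median of −0.48.

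At 6 and 12 h in roots all 6 COR genes rose, also when adjusted over the list alone. As in shoots, changes at these times cannot be told apart from those with the time of day. AT4G33980 rose by 5.35 ± 0.17 (SE; adjusted p = 1.5e-12) at 6 h, and COR15A rose by 1.77 ± 0.40 at 6 h and 4.67 ± 0.40 at 12 h (adjusted p = 0.0087 and 1.6e-07). The list median was 2.11 at 6 h and 4.47 at 12 h (camera adjusted p = 1e-14 and 4.3e-13; with an estimated correlation, adjusted p = 0.00057 and 0.0008). STZ read 2568 ± 1.28 (SD, n = 2) at 6 h against 531 ± 56.1 at 0.5 h, and was still up at 12 h (1.59 ± 0.25). GI rose by 0.56 ± 0.16 at 6 h and 1.23 ± 0.16 at 12 h, and LEA4-5 by 1.32 ± 0.29 and 4.16 ± 0.29. The photosynthesis gene LHCB4.2, already dim in roots, fell from 53.9 ± 20.3 to 4.27 ± 1.71 by 12 h (−2.13 ± 0.27). Totals were 840 higher and 383 lower at 6 h, and 1596 higher and 2854 lower at 12 h. The 6 h total of 1223 was 735, 764 and 750 without 0.5 h replicate 1, 6 h replicate 1 and 6 h replicate 2, and the 12 h total of 4450 was 2916 without 12 h replicate 1. The share of calls higher at 12 h was 35.9% as deposited, 52.7% (1994 higher, 1793 lower) with median centring, 45.3% after quantile normalization and 46.2% (1851 and 2157) after quantile normalization within each tissue.

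At 24 h in roots COR15A rose from 4.13 ± 4.78 (SD, n = 2) to 2257 ± 626 (7.34 ± 0.40 SE; adjusted p = 3.5e-10). LEA4-5 went from 4.52 ± 1.51 to 1266 ± 498 (6.40 ± 0.29) and COR27 from 0.937 ± 0.139 to 775 ± 173 (6.15 ± 0.19, adjusted p = 6.6e-13), all 3 from below an intensity of 30, so their order was not read. AT5G62360, AT1G16850, COR15B, AT1G68500 and AT4G33980 rose by between 5.10 and 6.58. All 6 COR genes rose, with a median of 5.46, or 5.67 above all genes (camera adjusted p = 1.5e-10; with an estimated correlation, adjusted p = 0.0017). CML38, STZ and GI were up by 1.97 ± 0.51, 1.26 ± 0.25 and 1.76 ± 0.16. Among the declines were those of AT4G10270 (292 ± 145 to 8.92 ± 8.07; −3.98 ± 0.35, adjusted p = 1.1e-07), AT1G33055 (441 ± 270 to 24.2 ± 2.51; −3.58 ± 0.43) and AT3G10040 (184 ± 127 to 6.15 ± 3.2; −3.43 ± 0.42), which are known as genes induced by low oxygen. Their 0.5 h arrays were far apart, while AT3G13760 fell between close replicates, from 204 ± 6.86 to 16.6 ± 3 (−3.01 ± 0.13, adjusted p = 3e-11). AT5G57785, AT5G10210, AT1G14120 and AT1G80180 fell by between 2.98 and 3.23.

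The smaller lists in roots at 24 h gave mixed counts. Of 8 ribosome biogenesis genes 1 rose (1 adjusted over the list alone), PRH75 by 0.87 ± 0.20 (SE; adjusted p = 0.0017; camera adjusted p = 0.26), and 2 rose after either rescaling. Of 3 starch genes DPE1 fell by 0.56 (adjusted p = 0.0073; 1 adjusted over the list alone; camera adjusted p = 0.76), a call lost after either rescaling. Of 5 photosynthesis genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.28), LHCB4.2 by 2.51, LHCB4.1 by 0.74 and RCA by 0.66, and 1 fell after either rescaling. In the heat shock list AT5G48570 fell by 1.09 (adjusted p = 0.0035) and the small heat shock protein gene AT1G53540 rose by 0.96 (adjusted p = 0.00063). PRL (−0.34 ± 0.17, adjusted p = 0.097), DFR (−0.14 ± 0.47, adjusted p = 0.84), UF3GT (0.37 ± 0.30, adjusted p = 0.32) and PYK10 (−0.01 ± 0.18, adjusted p = 0.98) did not pass, and none of the 3 root markers did, where 1 fell after quantile normalization within the tissue. In all, 2488 probe sets were higher and 5222 lower, 1249 and 1425 of them at least 2-fold. The share higher was 32.3% as deposited, 51.5% (3451 higher, 3246 lower) with median centring and 42.1% after quantile normalization.

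The changes of both tissues were compared by testing the difference of the changes, roots minus shoots. At 3 h AT1G51090 changed less in roots (5.77 to 17.5, against 6.19 to 484 in shoots; difference −4.16 ± 0.36 SE, adjusted p = 3e-06). AT1G22570, a transporter gene of the major facilitator family, went from 32.9 ± 5.38 (SD, n = 2) to 680 ± 17.3 in shoots and had 47.3 ± 2.73 and 51.6 ± 8.06 in roots (difference −3.91 ± 0.21, adjusted p = 1.5e-08). AT2G17660 had a difference of −3.88 ± 0.43. Positive differences were those of AT1G49200 (2.10 ± 0.33, adjusted p = 0.0012), the expansin-like gene EXLA3 (1.95 ± 0.35, adjusted p = 0.004) and AT2G23270 (2.19 ± 0.54, adjusted p = 0.045), and the last 2 lost their call under some settings. The COR genes changed less in roots, 3 of 6 (4 adjusted over the list alone), with COR15B at −3.70 ± 0.43 and a median of −1.97 (camera adjusted p = 4.8e-09; with an estimated correlation, adjusted p = 0.0027). GI also changed less in roots (−0.93 ± 0.22, adjusted p = 0.035), and the differences of STZ (−1.06 ± 0.35, adjusted p = 0.18) and CML38 (−2.45 ± 0.72, adjusted p = 0.11) did not pass. In all, 74 differences were positive and 256 negative. Their total of 330 was 218 without roots 0.5 h replicate 1 and 571 without roots 3 h replicate 1.

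At 24 h LTI30 was among the genes ranked outermost between the tissues on the log2(value + 10) scale, with a difference of −5.18 ± 0.30 (SE; adjusted p = 1.5e-08). In roots it stood at 878 ± 128 (SD, n = 2) at 0.5 h and at 7031 ± 556 at 24 h. COR47 was alike (182 ± 19.8 to 8723 ± 330 in shoots, 1323 ± 268 to 7335 ± 709 in roots, difference −3.04 ± 0.36). At 24 h LTI30 and COR47 read not far below the highest intensities on their arrays, 9380.7 and 10118 in shoots and 7950.5 and 8685.8 in roots. Whether an upper limit of the intensities has a part in these differences was not tested. Of the 6 COR genes 2 had a lower change in roots (3 adjusted over the list alone; median −0.81, camera adjusted p = 0.066), and after quantile normalization the median was −0.36 (camera adjusted p = 0.23), against −0.79 with median centring and −0.89, with 3 genes lower, after quantile normalization within each tissue. AT1G20030, of the thaumatin family, went from 5.61 ± 6.05 to 1002 ± 115 in shoots and from 13.8 ± 3.85 to 25.8 ± 2.7 in roots (−5.47 ± 0.39, adjusted p = 4.9e-08). AT1G80130, AT4G34950 and AT3G04010 had differences of −4.04, −3.65 and −3.62. AT4G33666 (5.49 ± 0.36), AT1G23390 (5.15 ± 0.31), AT2G20670 (5.04 ± 0.45), AT2G34620 (4.66) and AT1G13650 (4.62) fell in shoots and did not fall past the threshold in roots. There AT1G23390 rose from 126 to 230 (0.80, adjusted p = 0.0065) and AT2G20670 from 89.5 to 194 (1.03, adjusted p = 0.014), AT4G33666 read 26.6 and 43, and AT1G13650, at 1.09 and 0.523, was near the floor of the array. STZ (2.05 ± 0.35, adjusted p = 0.00028) and CML38 (2.0 ± 0.72, adjusted p = 0.043) had the higher change in roots, and GI changed less there (−2.30 ± 0.22, adjusted p = 9.7e-07). Ribosome biogenesis genes had a lower change in roots, 7 of 8 (7 adjusted over the list alone), with a median of −1.03 (camera adjusted p = 0.00092; with an estimated correlation, adjusted p = 0.36). Of 3 starch genes 2 had a lower change in roots (2 adjusted over the list alone), PWD by −1.97 ± 0.19, with a camera adjusted p = 0.039 and an adjusted p = 0.4 with an estimated correlation. In all, 2487 differences were positive and 2691 negative, and the larger side turned at 2-fold or more (1578 and 1484), with no filter (2644 and 2593) and without roots 0.5 h replicate 2 (2244 and 2205).

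**Figure D3:**
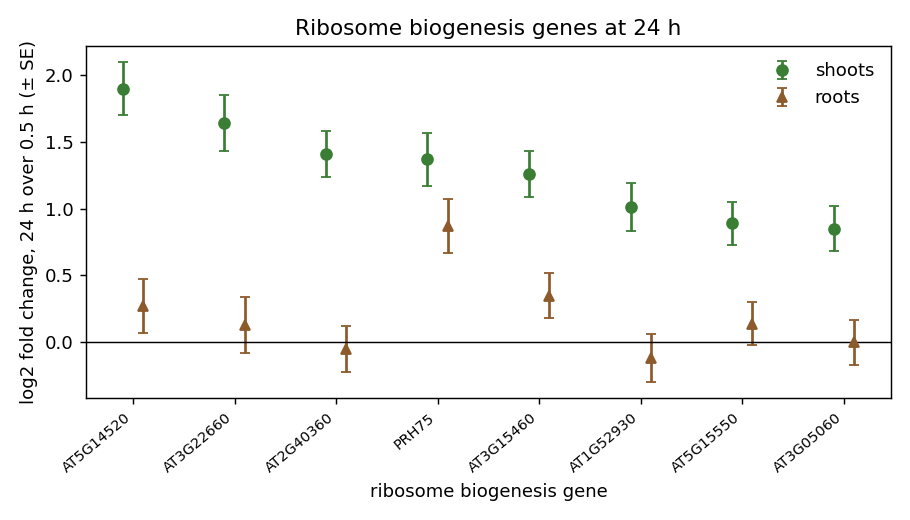
Log2 change at 24 h over 0.5 h (vertical axis) of the 8 measured ribosome biogenesis genes (horizontal axis), as the limma estimate from 2 arrays per group with its SE, circles for shoots and triangles for roots. All 8 lie above 0 in shoots, led by AT5G14520 at 1.90, and the highest in roots is PRH75 at 0.87.

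The 24 h changes of both tissues, which share no arrays, overlapped in direction. Among 16072 probe sets, 1354 were higher in both tissues where independent lists would share 479, and 2968 were lower in both where 1791 would be shared. Opposite calls were fewer than independent lists would give, 216 against 1005 for higher in shoots and lower in roots, and 274 against 853 for the reverse. Among the named genes LTI30, LEA4-5, COR15A, COR27, AT1G16850 and AT5G62360 rose in both tissues, and STZ fell in shoots and rose in roots. Across probe sets the fold changes correlated with r = 0.55 and rho = 0.48, and probe sets are not independent replicates. Of the 4322 shared calls 31.3% were higher as deposited, 54.1% (1955 higher, 1656 lower) with median centring, 45.1% (1687 and 2057) after quantile normalization and 44.5% (1655 and 2066) after quantile normalization within each tissue.

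Transcripts of the chloroplast genome and of nuclear photosynthesis genes were followed as separate lists, and the difference between the lists was not tested. Both lists, like the one of late embryogenesis abundant (LEA) proteins, were added after the data were seen. At 3 h in shoots 16 of 69 chloroplast-encoded genes rose and none fell (20 adjusted over the list alone), with psaC, a photosystem I subunit, going from 234 ± 24 (SD, n = 2) to 1608 ± 509 (2.69 ± 0.31 SE, adjusted p = 1.1e-05). The median was 0.46 (camera adjusted p = 2.8e-12; with an estimated correlation, adjusted p = 0.64), while none of 23 nuclear photosynthesis genes passed (median −0.04, camera adjusted p = 0.99). At 6 and 12 h 21 and 15 rose (camera adjusted p = 2.7e-11 and 0.00016; with an estimated correlation, adjusted p = 0.69 and 0.97), and at 1 h camera gave an adjusted p = 6.1e-11 and an adjusted p = 0.7 with an estimated correlation. At 24 h 11 rose (8 adjusted over the list alone), and the median of 0.14 (camera adjusted p = 0.032; with an estimated correlation, adjusted p = 0.98) turned to −0.03 after quantile normalization, where 1 gene fell and camera gave an adjusted p = 0.69. It was also −0.03 after quantile normalization within each tissue, where 5 fell, and 0.32 with median centring, where 14 rose and none fell. The 25S rRNA control probe set, which has no poly(A) tail to be primed from, read 212 and 246 on the 0.5 h shoot arrays, 889 to 1862 on all other shoot arrays and 1454 to 2885 on root arrays.

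In roots the chloroplast-encoded genes moved the other way. At 12 h 41 of 69 fell (45 adjusted over the list alone), led by cemA (859 to 155; −2.39 ± 0.30 SE, adjusted p = 1.2e-05), with a camera adjusted p = 4.8e-09 and an adjusted p = 0.75 with an estimated correlation. At 24 h 23 fell (19 adjusted over the list alone; median −0.55), with a camera adjusted p = 0.084 as deposited and 0.0025 after quantile normalization, and an adjusted p = 0.98 with an estimated correlation. With median centring 13 fell at 24 h, with a median of −0.35. The 24 h arrays were apart, with list means (log2) of 7.14 and 8.02, where the 0.5 h arrays had 8.13 and 8.19 and the 12 h arrays 7.09 and 7.20. The 25S rRNA control read 10.51 and 11.49 (log2) on these 24 h arrays in the same order, 11.39 and 11.24 at 0.5 h and 10.68 and 10.93 at 12 h. The ratio of the 3' to the 5' actin control, a sign of RNA quality, was 1.76 and 1.89 on the 0.5 h root arrays, 2.06 and 2.09 at 12 h and 2.05 and 2.17 at 24 h. At 3 h none of the 69 passed, the median was −0.44 (camera adjusted p = 3.8e-07) and the adjusted p = 0.8 with an estimated correlation. The list means (log2) on the 3 h root arrays were 7.94 and 7.43, so the size of this shift, and of the 3 h tissue difference, leans on replicate 2. Nuclear photosynthesis genes fell too, 8 of 23 at 12 h and 14 at 24 h (8 and 15 adjusted over the list alone; camera adjusted p = 0.03 and 0.017; with an estimated correlation, adjusted p = 0.97 and 0.93), and at 12 h 5 fell after quantile normalization (camera adjusted p = 0.053). In shoots at 24 h 1 of them rose and 12 fell (1 and 12 adjusted over the list alone), with PORB, which reduces protochlorophyllide, at 1.47 ± 0.38 and the thylakoid calcium sensor CaS at −1.23 ± 0.27 (camera adjusted p = 0.24, and 0.016 after quantile normalization; with an estimated correlation, adjusted p = 0.98 as deposited). At 1 h in roots none passed, and camera placed them higher (adjusted p = 0.0053), with an adjusted p = 0.82 with an estimated correlation, where the 0.5 h arrays stood apart (5.48 and 6.04). The tissue difference of the chloroplast-encoded genes had 8 of 69 lower at 3 h (25 adjusted over the list alone) and 22 lower at 24 h (22 adjusted over the list alone), with medians of −1.02 and −0.74. Camera gave adjusted p = 4.3e-23 and 0.00013, and with an estimated correlation adjusted p = 0.25 and 0.97. Of the nuclear photosynthesis genes 3 were higher and 5 lower in that difference at 24 h (median −0.22, camera adjusted p = 0.69), which turned to 4 higher and 2 lower (median 0.04) after quantile normalization and to 5 and 2 (median 0.07) within each tissue.

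The LEA list shares 4 of its 6 measured genes with the COR list and 1 with the abscisic acid list, so it is not separate evidence. All 6 rose at 24 h in each tissue (6 adjusted over the list alone), with medians of 6.97 in shoots and 4.41 in roots, and 5 rose in roots after quantile normalization. Camera gave adjusted p = 1.5e-08 in shoots and 4.4e-08 in roots, and adjusted p = 0.012 and 0.013 with an estimated correlation. At 3 h 4 rose in shoots (4 adjusted over the list alone; camera adjusted p = 2.5e-07; with an estimated correlation, adjusted p = 0.017). In roots 1 rose at 3 h (2 adjusted over the list alone; camera adjusted p = 0.005; with an estimated correlation, adjusted p = 0.25). The change was lower in roots for 2 genes at 3 h and 4 at 24 h (3 and 4 adjusted over the list alone; camera adjusted p = 0.00051 and 0.0033; with an estimated correlation, adjusted p = 0.13 and 0.23). The outermost of these were COR15B (−3.70) and COR47 (−2.42) at 3 h, and LTI30 (−5.18) and COR47 (−3.04) at 24 h.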

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

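The tests of the tissue difference, of the splits of the arrays and of shoot RNA on a root array were chosen before their results were seen, and the other tests of this part only afterwards.

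All results listed here drew attention because the change with time in the cold differed between roots and shoots by a test of that difference, given as roots minus shoots on the log2 scale. At 3 h 330 probe sets differed. Among named genes the differences were −2.90 for AT5G62360, −1.90 for AT1G11210, −4.16 for AT1G51090, −3.91 for AT1G22570 and −3.88 for AT2G17660. Positive differences at 3 h were 1.07 for P1R1, 1.87 for AT5G11070, 2.19 for AT2G23270, 2.10 for AT1G49200 and 1.95 for EXLA3. List medians at 3 h were −1.97 for cold-regulated genes, −1.02 for chloroplast-encoded genes, −1.19 for LEA proteins, −0.24 for hypoxia genes and −0.49 for mitochondrion-encoded genes. Of these lists only the cold-regulated genes passed with an estimated correlation.

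At 24 h 5178 probe sets differed. Genes that rose at 24 h in shoots had differences of −5.18 (LTI30), −1.73 (LEA4-5), −1.65 (AT1G16850), −2.44 (AT1G51090) and −2.42 (AT1G11210). Those that fell at 24 h in shoots had differences of 5.49 (AT4G33666), 3.12 (EXPA8), 4.66 (AT2G34620), 4.62 (AT1G13650), 5.15 (AT1G23390), 3.83 (AT1G55960), 1.34 (AT4G24780), 4.23 (AT2G27420) and 5.04 (AT2G20670). Genes that fell at 24 h in roots had differences of −2.90 (AT4G10270), −3.37 (AT1G33055), −3.17 (AT3G10040), −2.61 (AT5G10210), −1.32 (AT1G14120) and −2.99 (AT3G13760). The outermost negative differences also held AT1G20030 (−5.47), AT1G80130 (−4.04), AT4G34950 (−3.65) and AT3G04010 (−3.62). Several of these genes stood near the floor of the array in the tissue without a change, such as AT3G13760 in shoots at 0.72 and AT1G13650 in roots at 1.09. List medians at 24 h were −1.15 for starch genes, −1.03 for ribosome biogenesis genes, −0.74 for chloroplast-encoded genes, −1.68 for LEA proteins and −1.74 for hypoxia genes. None of these lists passed with an estimated correlation. The hypoxia list was drawn up after the fall of AT4G10270, AT1G33055 and AT3G10040 in roots at 24 h was seen, so its median is not separate evidence. A difference in biology between the tissues stays open for all results listed here and was not tested apart from the tissue label.

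Of 69 chloroplast-encoded genes 17, 16, 21 and 15 were higher in shoots at 1, 3, 6 and 12 h than at 0.5 h, where the 25S rRNA control was also lowest, with adjusted p = 0.7, 0.64, 0.69 and 0.97 for the list with an estimated correlation, and at 24 h their median of 0.14 turned to −0.03 after quantile normalization and was 0.32 with median centring. After quantile normalization camera with its preset correlation still placed the list higher at 3 h (limma, unadjusted p = 5.1e-11), with a median 0.48 above all genes. Both values compare the list with other genes, so a shift of whole arrays largely cancels and they cannot decide on scaling. The list median itself was 0.46 as deposited, 0.41 after quantile normalization (14 genes higher in place of 16) and 0.48 with median centring (15 higher). Neither rescaling thus removed the shift, though as deposited the list does not pass camera with an estimated correlation (p = 0.12, adjusted 0.64). A candidate explanation is that more RNA without poly(A) tails was carried over on some arrays: between the replicates of the 12 groups, the difference in chloroplast-encoded level followed that in 25S rRNA (r = 0.72, permutation p = 0.0092, adjusted 0.0092 over 2 relations, Spearman's rho 0.78, p = 0.0045). The relation was 0.58 (permutation p = 0.076, n = 10) without the roots 24 h and shoots 24 h groups, so it partly rests on them, and for mitochondrion-encoded genes it was 0.80 (permutation p = 0.0029, adjusted 0.0057). Within shoots it was not tested. There the differences in 25S rRNA and chloroplast-encoded level were opposed at 1 h (−0.08 and 0.61) and 6 h (−0.41 and 0.01). They had the same sign at 0.5 h (0.22 and 0.15), 3 h (0.10 and 0.27), 12 h (−0.52 and −0.34) and 24 h (0.68 and 0.16). The largest in both were those of roots at 24 h (0.99 and 0.88). A true rise in shoots in the cold stays open beside such a carry-over and was not tested.

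Shoots 1 h replicate 1 and roots 3 h replicate 2 differed from their partners in shared probe sets: the replicate differences of these groups correlated at −0.32, where the next largest of 36 cross-tissue pairs was 0.11 in size, and within roots the 3 h difference also correlated with those at 1 h (−0.42), 6 h (0.32) and 24 h (0.21), so it is not particular to this pair. Gene length is argued against, with rho = 0.05 over 8567 genes. Roots 3 h replicate 2 may hold some shoot RNA, since 20 of 23 nuclear photosynthesis genes were higher on it by a median of 0.68, and 133 of 159 probe sets abundant in shoots (83.6%) were higher, by a median of 1.13% of their shoot level, but the nuclear photosynthesis mean of 6.19 (log2) lay near those of 2 other root arrays (6.04 and 6.02), the 0.5 h root arrays were also apart (5.48 and 6.04), and chloroplast-encoded transcripts were lower on it by −0.48, so this stays open. That RNA as the cause of the shared deviation is argued against, since the correlation was −0.31 over the 11382 probe sets not higher in shoots. A batch of arrays or RNA shared by both cannot be told apart from other causes, as the labels give no batch, and no biological explanation was tested.

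Hypoxia genes, 19 measured of 40 listed from general knowledge, were lower in roots at 24 h, with 12 lower, 4 higher and a median of −1.72. After quantile normalization 10 of the 12 still fell, with a median of −1.50 relative to all genes. Both were nearly given, since the 12 were chosen by their fall and a shift of whole arrays largely cancels in that median. The list median itself was −1.60 after quantile normalization and −1.52 with median centring, so neither rescaling removed the fall. A high start on roots 0.5 h replicate 1 as the whole cause was tested with another baseline, where 13 members fell against 1 h, among them all 12. The list means were 8.08 and 7.39 (log2) at 0.5 h, 8.37 and 8.45 at 1 h and 6.34 and 6.65 at 24 h. As the 1 h arrays stood above both 0.5 h arrays, a fall against them was nearly given and cannot decide this. Replicate 2 of 0.5 h, at 7.39, also lay above both 24 h arrays, but it is 1 array. A first demand, that more than 8 of the 12 still fall without that array, was not met, since 8 did (median −1.31), and the 1 h arrays were taken in its place after this was seen, so a part in the size of the fall stays open. Fry, which keeps the correlation between members, gave an unadjusted p = 0.0018 (adjusted 0.0088). It was run on all 19 members, with the 3 genes whose fall in this comparison led to the list, so it cannot decide on replicate noise. Chance against other genes stays open too, since camera gave p = 0.088 (adjusted 0.24) with its preset correlation and p = 0.54 (adjusted 0.98) with an estimated one. Random lists of unrelated genes, with the median of −1.23 without these 3 genes at percentile 0 of 10000, do not allow for genes that vary together. A fall during chilling was not tested apart from time.

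Of 100 splits of the 24 arrays, 1, the real one, gave as many as 13949 probe sets that differed between roots and shoots. A split that mixes the tissues within a time puts their difference into the spread. Fewer calls were thus nearly given, and the splits add little to the tissue labels and markers. The highest other split gave 10583 and kept 20 of the 24 arrays on the side of their tissue, so it follows the structure of these samples.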

How the results depend on the processing

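The baseline of 1 h and the omission of shoots 1 h replicate 1 and roots 3 h replicate 2 were chosen only after the results were seen. These are called the deviating arrays here, though a difference within a pair does not show which of its arrays deviates. No direction turned under any alternative for the 80 named-gene results. These genes were chosen for the largest changes past the threshold, most with all arrays of the compared groups apart, so this was nearly fixed by the choice. Of the counts, the larger side (higher or lower) turned in 11 of 187 comparisons over the settings and in 7 of 88 with an array left out. Over the settings these were shoots at 6 h, with 50.1% higher after quantile normalization, 52.1% with median centring, 52.9% at a mean intensity of at least 100 and 73.7% at 2-fold or more, against 44.9%. Roots at 12 h turned from 35.9% to 52.7% with median centring and 56.6% at 2-fold or more, roots at 24 h from 32.3% to 51.5% with median centring, the overlap from 31.3% to 54.1% with median centring and 52.6% at 2-fold or more, and the tissue difference at 24 h from 48% to 50.5% with no filter and 51.5% at 2-fold or more. With an array left out they were shoots at 6 h without any 1 of its 4 arrays (50.8% to 54.8%), shoots at 1 h without 1 h replicate 2 (64.7% to 38.9%), roots at 3 h without 3 h replicate 1 (87% to 45.3%) and the tissue difference at 24 h without roots 0.5 h replicate 2 (50.4%). Over the settings, 1025 of 1050 named-gene comparisons kept their call and 25 lost it, and with single arrays left out 602 of 624 kept it and 22 lost it. The losses fell on AT2G02630, AT2G23270, AT3G06070, EXLA3, AT5G65860, AT3G07350, AT1G04770 and AT5G57785, all in the 3 h comparisons. Of the counts, 165 of 191 comparisons over the settings and 69 of 88 with an array left out stayed within 1.5-fold. A demand for a mean intensity of at least 100 left 7154 probe sets, so fewer were tested: the counts were 2082, 3326 and 4387 in shoots at 6, 12 and 24 h, 2211 and 3834 in roots at 12 and 24 h, 2803 for the tissue difference at 24 h, 6475 for roots against shoots and 2356 for the overlap. A demand for a 2-fold change lowers counts by construction, to 115, 512, 1103, 2354 and 3595 in shoots from 1 to 24 h, to 230, 610, 1520 and 2674 in roots from 3 to 24 h, to 3062 for the tissue difference at 24 h, to 5579 for roots against shoots and to 1086 for the overlap. The fit on shoots alone gave 205 at 1 h, and the cause was not tested. With 1 h as the baseline the 3 h counts were 571 in shoots and 162 in roots. Without both deviating arrays they were 167 in shoots at 1 h and 256 in roots at 3 h. The cause was not tested for either. With an estimated correlation 16 list shifts passed in place of 43. Quantile normalization gave 42, of which 40 were shared.

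With each array left out in turn, the lone array of a group was assumed to vary like the other groups. The counts ranged from 112 (without shoots 0.5 h replicate 2) to 2211 (without shoots 1 h replicate 2) in shoots at 1 h, with 147 without 0.5 h replicate 1 and 118 without 1 h replicate 1. In shoots they ranged from 756 to 841 at 3 h (756, 765 and 780 without 0.5 h replicate 1, 0.5 h replicate 2 and 3 h replicate 2), and from 2214 to 2400 at 6 h (2214, 2236 and 2246 without 0.5 h replicate 1, 0.5 h replicate 2 and 6 h replicate 2). In roots they ranged from 205 (without 0.5 h replicate 1) to 1254 (without 3 h replicate 1) at 3 h, with 232 without 3 h replicate 2. In roots at 6 h the range was 735 to 883 (735, 764 and 750 without 0.5 h replicate 1, 6 h replicate 1 and 6 h replicate 2), at 12 h 2916 (without 12 h replicate 1) to 3077, and at 1 h 2 (without 0.5 h replicate 1) to 4. The tissue difference at 3 h ranged from 218 (without roots 0.5 h replicate 1) to 571 (without roots 3 h replicate 1). The other ranges, 4788 to 5103 and 7030 to 7389 in shoots and 5921 to 6740 in roots at 12, 24 and 24 h, 4178 to 4655 for the tissue difference at 24 h, 13775 to 14008 for roots against shoots and 3483 to 3912 for the overlap, stayed within 1.5-fold.

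The replicate numbers did not pair the arrays in 1 way over all groups: over 66 pairs of groups the correlation of replicate differences ran from −0.45 to 0.33, with 9 over 0.1 and 10 under −0.1. Within roots it was 0.33 between 0.5 and 1 h, 0.08 to 0.32 among 3, 6, 12 and 24 h, and −0.45 to −0.06 between these early and late times. Root replicates thus shared some variation, with the numbers reversed between early and late times, which a block on the number cannot take out. With the number as a replicate block the counts were 386, 1173, 3348, 6399 and 8491 in shoots and 3, 370, 1155, 4279 and 7572 in roots, 319 and 5033 for the tissue differences, 13903 for roots against shoots and 4217 for the overlap. As a random block within each time the number had a consensus correlation of −0.03, with 8608 calls in shoots at 24 h and 317 for the tissue difference at 3 h. Between 11342 and 13649 of 22746 probe sets per array reached an intensity of 30, and below it changes are compressed by the pseudocount.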

Other observations

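Every list in this part was added after the data were seen, so its counts and tests were chosen only afterwards. Cell wall genes split in both tissues. In shoots at 24 h 5 of 23 expansin and xyloglucan hydrolase genes rose and 10 fell (5 and 10 adjusted over the list alone), with the expansin-like gene EXLA1 at 4.68 ± 0.25 (SE; 73.2 to 2120), EXLA2 at 3.09 ± 0.26 and the hydrolase gene EXGT-A3 at −2.53 ± 0.24. In roots at 24 h 7 rose and 8 fell (7 and 9 adjusted over the list alone), with EXLA1 (4.47 ± 0.25), EXLA3 (4.44 ± 0.25) and EXLA2 (4.37 ± 0.26) up and EXPA4 (−2.71 ± 0.23) down. The median there was −0.45 while the mean of 0.08 and camera pointed up (adjusted p = 0.84), and in shoots the median was −0.45 (camera adjusted p = 0.95). After quantile normalization these medians were −0.33 in roots and −0.23 in shoots, and with median centring −0.25 and −0.27. At 3 h 3 rose in shoots, led by XTH18 (2.78 ± 0.31), and none fell, with a median of −0.13 and a mean of 0.15 (camera adjusted p = 0.44). In roots at 3 h EXLA3 (2.34 ± 0.25) and EXLA1 (1.94 ± 0.25) rose (camera adjusted p = 0.24). The tissue difference at 24 h was positive for 7 genes, with XTH20 at 3.51 ± 0.28 (67.9 to 928 in roots), and negative for 3, with XTH21 at −1.97 ± 0.40 (camera adjusted p = 0.53).

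Genes of protein folding in the endoplasmic reticulum and cytosol also split, with 10 of 24 higher and 10 lower in shoots at 24 h (10 and 10 adjusted over the list alone; median 0.01, camera adjusted p = 0.34), and 11 higher and 7 lower with median centring (median 0.19). BZIP60, a transcription factor of the unfolded protein response, rose by 2.96 ± 0.16 (SE; 82.2 to 707) and Fes1A, a nucleotide exchange factor of Hsp70, by 2.64 ± 0.16, while DER2.1, a derlin, fell by 1.23. In roots 5 rose and 8 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.69), with Fes1A at 1.35 ± 0.16, BZIP60 at 1.25 ± 0.16 and Hop3 at −1.54 ± 0.16, and the larger side turned with median centring, to 8 higher and 5 lower (6 and 7 after quantile normalization). The change of BZIP60 was lower in roots by −1.71 ± 0.22 (adjusted p = 2e-05), among 4 higher and 6 lower differences (camera adjusted p = 0.41; 2 and 8 after quantile normalization). Of 14 auxin genes 2 rose and 2 fell in shoots at 24 h (2 and 2 adjusted over the list alone; camera adjusted p = 0.59; 3 and 2 after either rescaling), with the repressor genes IAA29 at 1.69 ± 0.31 and IAA18 at −1.82 ± 0.27. In roots 2 rose and 4 fell (3 and 5 adjusted over the list alone; median −0.10, mean −0.16, camera pointing up with adjusted p = 0.99), where the median turned to 0.08 after quantile normalization and 0.10 with median centring, with GH3.17, which joins auxin to amino acids, from 457 to 60.2 (−2.84 ± 0.27, adjusted p = 3.3e-07). The tissue difference at 24 h was positive for 4 auxin genes and negative for 5 (camera adjusted p = 0.76).

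Among 11 mitochondrion-encoded genes cox1 (1.26 ± 0.16 SE, adjusted p = 4.4e-05) and nad4 (1.01 ± 0.30, adjusted p = 0.047) rose in shoots at 3 h (2 adjusted over the list alone; 1 rose after quantile normalization; camera adjusted p = 0.044; with an estimated correlation, adjusted p = 0.93). At 1 h 1 rose (5 adjusted over the list alone; camera adjusted p = 0.0065; with an estimated correlation, adjusted p = 0.75). At 24 h cox1 alone passed in shoots, the median was −0.28 (−0.06 after quantile normalization) and camera pointed up (adjusted p = 0.9). In roots 1 rose and 5 fell at 12 h (1 and 6 adjusted over the list alone; camera adjusted p = 0.26), and 1 rose and 3 fell at 24 h (1 and 5 adjusted over the list alone; camera adjusted p = 0.99), where 2 rose and none fell with median centring. The list means (log2) were 6.68 and 7.49 on the 24 h root arrays, with 25S rRNA at 10.51 and 11.49 in the same order, and 7.49 and 7.31 at 0.5 h, so replicate 2 did not lie below the 0.5 h arrays. None passed in the 3 h tissue difference (1 adjusted over the list alone; camera adjusted p = 0.0095; with an estimated correlation, adjusted p = 0.77). The 25S rRNA control was lowest on the 0.5 h shoot arrays, at 212 and 246.

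Of 19 hypoxia genes none passed in roots at 1 h, by limma or when adjusted over the list alone, with a median of 0.53 (camera adjusted p = 2.6e-14; with an estimated correlation, adjusted p = 0.099). The list means (log2) of the replicates were apart in roots at 0.5 h (8.08 and 7.39) and 3 h (8.23 and 7.31), and at 6 h replicate 2 was at 7.82 and replicate 1 lower, against 8.37 and 8.45 at 1 h. In roots 3 rose and 6 fell at 6 h (camera adjusted p = 0.5), 4 rose and 8 fell at 12 h (camera adjusted p = 0.34), and 4 rose and 12 fell at 24 h (4 and 13 adjusted over the list alone; camera adjusted p = 0.24). In shoots 3 rose at 3 h, CML38, AT5G47060 (2.81 ± 0.22 SE) and AT4G17670 (1.37 ± 0.18), with a camera adjusted p = 0.0016 and an adjusted p = 0.75 with an estimated correlation. In shoots at 24 h 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.2), with AT5G47060 at 3.76 ± 0.22 and AT4G27450 at −3.09 ± 0.32. The tissue difference was lower in roots for 2 genes at 3 h (3 adjusted over the list alone; camera adjusted p = 0.0033; with an estimated correlation, adjusted p = 0.79). At 24 h it was higher for 1 and lower for 11 (1 and 11 adjusted over the list alone). Camera gave an adjusted p = 0.0014, and an adjusted p = 0.75 with an estimated correlation. Among the 11 were AT5G44730 at −3.26 ± 0.39 and AT3G27220 at −3.22 ± 0.38. The 3 genes whose fall in roots at 24 h led to the list are also among them: AT4G10270 (−2.90), AT1G33055 (−3.37) and AT3G10040 (−3.17). The 24 h counts and tests hold these 3 genes, so they are not separate evidence for the list.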
